A study of Homo sapiens with 6 samples.

How the data were processed

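RNA from mouse embryonic fibroblasts, wild type or knockout for MLL1 (gene Kmt2a), was labelled with biotin after amplification with a NuGEN Ovation kit, per the labels' protocols, and hybridised to Affymetrix arrays. In all 6 samples were used, in 3 groups taken from the titles: wild type in DMSO (2 arrays), knockout in DMSO (3 arrays) and knockout in AUY922 (1 array). The values deposited by the authors are array signal intensities on a linear scale, 1 per probe set and array. MAS5, with no version given, is named in the submitters' processing notes. In the deposited table each array has a 2% trimmed mean of 500, so the values were already scaled between arrays, and no further step between arrays was applied in the main analysis. The scanner files and wild-type cells in AUY922 were not analysed here, so the difference between genotypes in the response to AUY922 was not tested. For arrays the number of arrays limits the precision.

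The table holds 45101 probe sets, of which 64 are array controls and were left out of all fits. Gene symbols came from a table of the array's annotation of 2016. By it, 34945 probe sets have 1 gene symbol, 932 have several and 9160 have none, and only the former were named. A table of human genes (assembly GRCh38.p14) was used for symbols alone, in the check of genes with no human counterpart, and none of its coordinates were used. None of the array's genes was placed on a genome.

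Intensities were transformed as log2(signal + 32), so that fold changes understate those of dim genes. Probe sets in the upper 60% by mean log2 over all 6 arrays were kept (27022 probe sets), and each gene was represented by its probe set with the highest mean, which left 12427 genes. limma 3.58.1 in R 4.3.3 was used with lmFit on the 3 group means, contrasts.fit and eBayes with a trend, and Benjamini-Hochberg adjustment over all genes at 0.05. All 6 arrays shared 1 estimate of the spread, which the lone AUY922 array needs. The median SD between replicates was 0.33 on the log2 scale in wild-type and 0.15 in knockout DMSO arrays. The labels do not say that the replicates come from separate cultures, so p-values of single genes measure only the spread between these samples, which may be technical. Where signals are given as mean ± SD they are deposited intensities.

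Before the data were examined, the groups, tests, 30 gene lists, most alternatives and the rule for named genes were fixed. Lists of at least 5 measured members (26) were tested with camera at a preset correlation of 0.01, adjusted over the lists, with camera at an estimated correlation and fry as alternatives. Calls were lost with an estimated correlation also where the estimate lay below the preset one. Such a loss is therefore no sign by itself of correlation between the genes of a list. For the lone array each list's median was also ranked among 10000 random lists matched on mean signal. The lists cover the heat shock response, HSP90 co-chaperones and heat shock factors, the unfolded protein, integrated stress, NRF2, p53, interferon and NF-kappaB responses, immediate-early genes, the proteasome, cytosolic ribosome, oxidative phosphorylation, glycolysis and hypoxia, cholesterol synthesis, the cell cycle, the Hox clusters, other MLL1-associated targets and MLL complexes. Markers of fibroblast matrix, smooth muscle, skeletal muscle, neural, macrophage, epithelial, endothelial, adipocyte, skeletal and prostate cells were included, and the histone list had 0 members matched by symbol.

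The genes named were, for each comparison, the 8 largest rises and 8 largest falls among genes that passed and whose arrays did not overlap between groups, filled where fewer passed with the genes of largest moderated t in that direction whose arrays did not overlap, given as values. To these were added Kmt2a and up to 4 members with the largest differences of each list that passed camera and of the heat shock, Hox and MLL complex lists. Other genes named were chosen after their values were seen. The alternatives were offsets of 1 and 100, quantile normalization, median centring, no filter or a filter at the upper 40%, other rules for the probe sets of a gene, eBayes without trend or robust, array weights, a minimum difference, the replicate number as a block, the knockout arrays alone and leaving out each array. The fits were tested on simulated data with 200 of 12427 genes changed. The spread of each gene was an SD observed on 2 wild-type or 3 knockout DMSO arrays, taken as true and shuffled over genes. With each group at its own spread, the drug comparison recovered 52% of rises of 2, 2% of rises of 1 and 0% of falls of 1 on the log2 scale over all 6 arrays, and 64%, 4% and 16% in the knockout arrays alone. The genotype comparison recovered 80% of rises of 2 and called 189 of 12227 unchanged genes. Its true calls there were 23, 40, 44 and 26 of 50 genes each, for changes of 1, 2, 3 and -1. False calls thus outnumbered true ones, far above the share that the adjustment is set to hold. With both groups at the knockout spread it called 5 unchanged genes. Figures were drawn with matplotlib 3.10.9.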

Results

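Gene expression was measured on 6 Affymetrix mouse arrays hybridised with RNA of mouse embryonic fibroblasts (MEFs), cells grown out of mouse embryos. The cells were wild type or knockout for MLL1, the histone H3 lysine methyltransferase encoded by Kmt2a, and all had been kept with doxycycline at 100 ng/ml for 3 days. They were then given for 3 h either the vehicle, 0.1% dimethyl sulfoxide (DMSO), or 100 nM AUY922, an inhibitor of the chaperone HSP90. There were 2 arrays of wild-type cells in DMSO, 3 of knockout cells in DMSO and 1 of knockout cells in AUY922. The labels name the organism as human, whereas the design text names MEFs and the probe sets are those of a mouse array. The free-text descriptions of several samples name other treatments and cell lines than their titles, and the groups follow the titles and genotype and treatment fields.

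Every array had a 2% trimmed mean signal of 500, but the wild-type arrays stood apart in each other property examined. Their median signals were 237 and 251.2, against 63.9 to 69 on the 3 knockout DMSO arrays and 64.3 on the AUY922 array. The hybridisation controls, bacterial and phage transcripts added in fixed amounts, had geometric mean signals of 103475 and 103929 on the wild-type arrays and of 4939 to 8584 on the knockout arrays, AUY922 included. These signals are relative to the common trimmed mean, so they do not show how bright the arrays were before scaling. The 3'/5' signal ratio of the Gapdh control was 11.8 and 19.0 on the wild-type arrays and 1.54 to 1.99 on the knockout arrays. That of the Actb control was 14.3 and 15.7 against 1.88 to 2.84. Across probe sets, which are not independent replicates, Pearson's r of log2 signals was 0.82 between the wild-type arrays, 0.64 to 0.66 between wild-type and knockout arrays and 0.985 to 0.996 among the 4 knockout arrays.

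**Figure D1:**
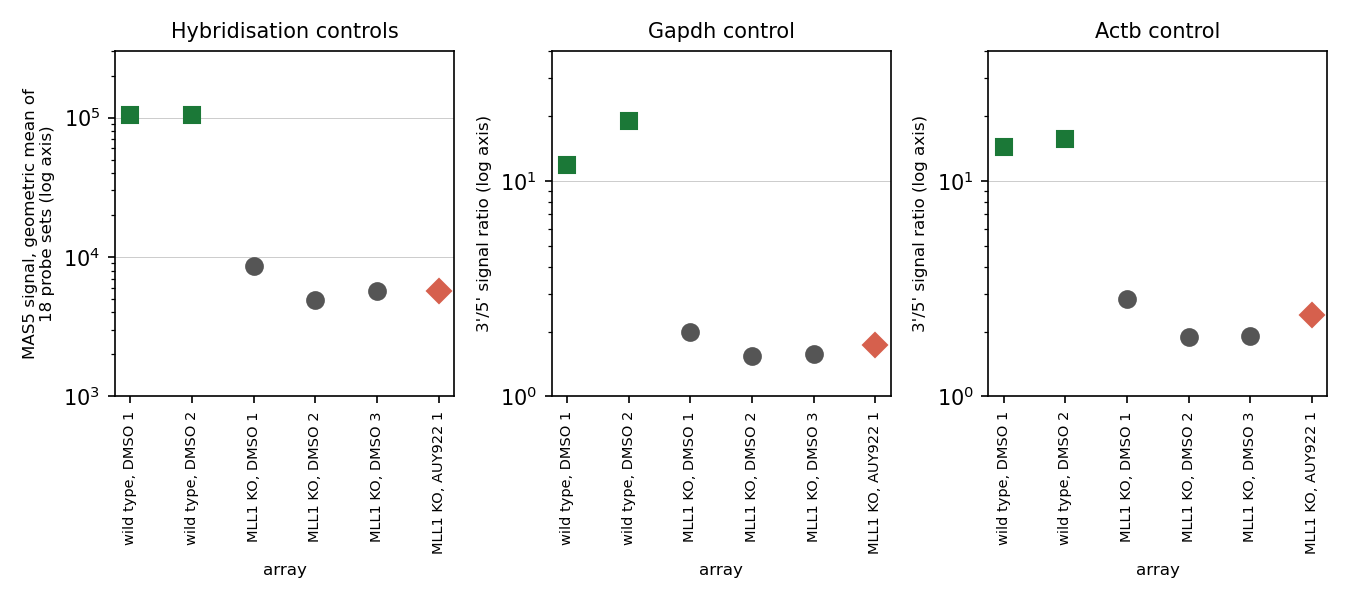
Hybridisation control signal (geometric mean MAS5 signal of 18 probe sets, log axis) and the 3'/5' signal ratios of the Gapdh and Actb controls (log axes), with 1 point per array. The 2 wild-type arrays lie above all 4 knockout arrays in each panel.

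The genotype comparison asks which transcripts differ in MLL1 knockout cells kept in vehicle. Kmt2a itself was lower in the knockout cells. The probe set with its higher mean had signals of 1501 and 656.8 in wild-type cells and of 155.9, 287.1 and 181.9 in knockout cells, a log2 difference of -2.13 (SE 0.42, 4.39-fold lower, limma with Benjamini-Hochberg adjustment, adjusted p = 0.00519, 2 against 3 arrays). The gene's other probe set had 704.7 and 851.8 in wild-type cells and 124.5 to 166.3 in knockout cells, 4.64-fold lower. On the AUY922 array the same probe sets had signals of 176.5 and 237.8. Whether either probe set lies in the deleted part of the gene is not given in the sources used here. Of 12427 genes tested, 3702 passed as lower in this comparison, and the wild-type arrays stood apart technically. The fall of Kmt2a is therefore not told apart from the difference between the arrays.

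Hox genes, the clustered homeobox genes that pattern the body axis and are known targets of MLL1, were lower in knockout cells as a group. Of 7 measured genes of the HoxA cluster 6 fell, 0 rose and 1 did not pass, with a median log2 difference of -3.78. Of 17 measured genes of the HoxB, HoxC and HoxD clusters 11 fell, 3 rose and 3 did not pass, with a median of -3.27. The counts adjusted over the list alone were the same as those adjusted over all genes. Hoxd10 had a mean signal of 27161 ± 7408 (SD, n = 2) in wild-type and 7.4 ± 3.27 (SD, n = 3) in knockout cells. Its knockout signals lay below the offset of 32, so the size of its log2 difference, -9.41 (SE 0.27), depends on the offset and ran from -11.72 to -7.96 over the settings tried. Among the others that fell, the log2 difference was -6.13 (SE 0.33) for Hoxc9, -5.98 (SE 0.26) for Hoxc8, -5.37 (SE 0.19) for Hoxa5, -4.89 (SE 0.25) for Hoxb5, -4.19 for Hoxa11, -4.10 for Hoxa3 and -3.78 for Hoxa9. Most of these sizes depend on the settings too, with ranges of -7.87 to -4.86 for Hoxc9, -6.67 to -5.13 for Hoxc8, -5.71 to -3.96 for Hoxb5 and -4.41 to -2.80 for Hoxa11, whose knockout signals were low, and -4.34 for Hoxa5 with probe sets open to cross-hybridisation avoided and -4.71 for Hoxa9 with the mean of its probe sets. Hoxd9, Hoxd8 and Hoxb9 went the other way and rose by 3.46, 1.99 and 0.73. Both Hox lists passed limma's camera test (adjusted p = 0.00699 for HoxA and 0.00887 for the other clusters). Neither call held with an estimated correlation (adjusted p = 0.401 with an estimated correlation for each). The estimates were -0.106 and 0.0065, below the preset 0.01, so a higher correlation between genes does not account for the loss. With an estimated correlation the test rests on the 3 residual degrees of freedom of the fit. At the preset one it takes them from the number of genes. Both directions were kept after quantile normalization, with medians of -3.60 and -2.97. The wild-type arrays in which these genes were bright are those whose hybridisation controls had a 16.2-fold higher scaled signal and whose 3'/5' ratios were raised.

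**Figure D2:**
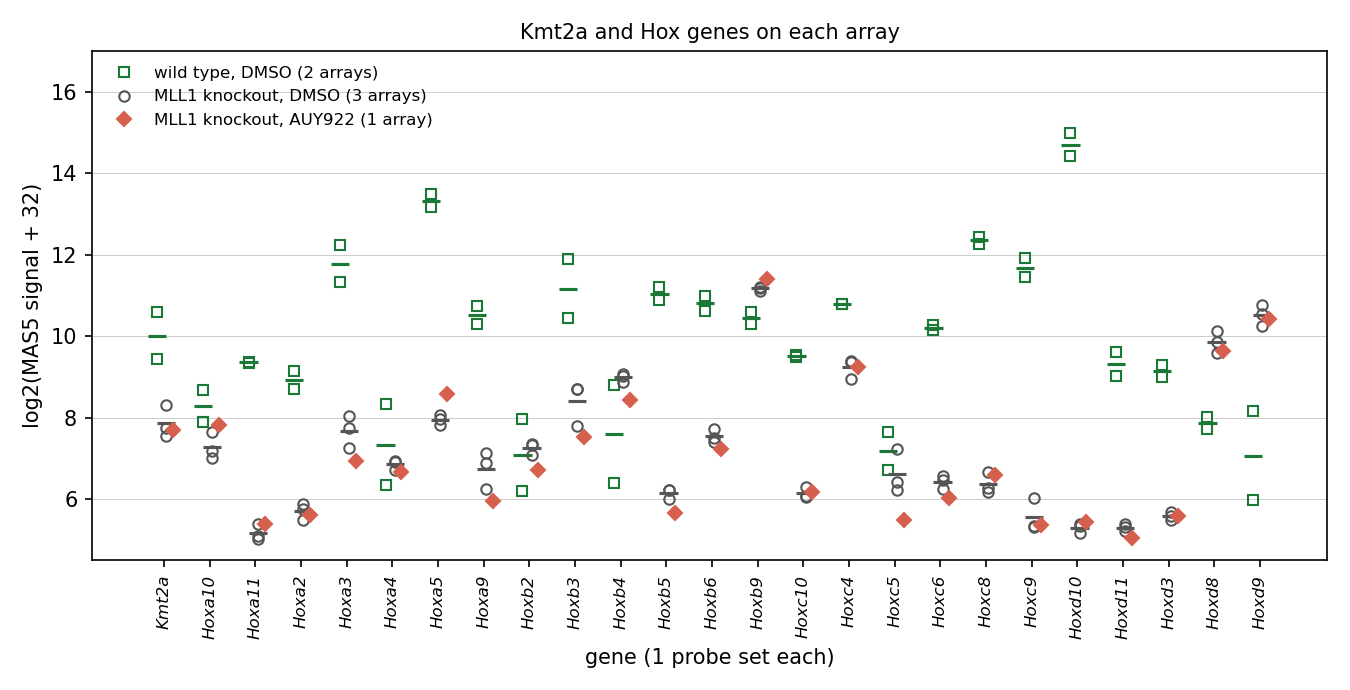
Signal, as log2(MAS5 signal + 32), of Kmt2a and the 24 measured Hox genes on each array, with wild-type DMSO arrays as squares, knockout DMSO arrays as circles, the AUY922 array as a diamond and horizontal bars for group means. Wild-type squares lie above the knockout circles for most genes, with Hoxb9, Hoxd8 and Hoxd9 among those that go the other way.

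Genes for other parts of MLL-type histone methyltransferase complexes moved both ways, with 8 of 23 higher, 9 lower and 6 not passing. Over all genes tested 65.0% passed, so the number passing in this or another list is no result about the list by itself. Kmt2d, which encodes another histone H3 lysine 4 methyltransferase, fell by 3.65 on the log2 scale (SE 0.21, adjusted p = 7.6e-05, limma). Men1, which encodes the MLL partner menin, rose by 3.34 (SE 0.32). Psip1, which encodes the chromatin tether LEDGF, rose by 2.32 (SE 0.16) and Aff4, which encodes a scaffold of the super elongation complex, by 2.26 (SE 0.16). After quantile normalization Kmt2d was at -1.82, and with the mean of the probe sets of each gene Men1 was at 1.47, Psip1 at 1.28 and Aff4 at 1.17. The list as a whole did not pass camera (adjusted p = 0.985, 0.985 with an estimated correlation). Its median was -0.24 and its mean 0.07, the sign of camera's direction.

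Of 31 measured cell-cycle genes 20 rose in knockout cells, 1 fell and 10 did not pass, both over all genes and adjusted over the list alone. Kif20a, a kinesin of cytokinesis, rose 11.6-fold (log2 difference 3.54, SE 0.44), with 4.34 without wild-type replicate 1 and 2.74 without wild-type replicate 2. Aurkb, a mitotic kinase, rose 8.61-fold (3.11, and 3.88 after quantile normalization) and Kif11, the kinesin that separates spindle poles, 7.96-fold, where the other 2 probe sets of Kif11 had log2 differences of -0.43 and 0.01. Ccne2, a G1/S cyclin, rose by 2.57 on the log2 scale, with wild-type signals of 262.4 and 24.2. Its difference was 3.77 without wild-type replicate 1 and 1.38 without wild-type replicate 2, and it did not pass without knockout DMSO replicate 1 (adjusted p = 0.0527, range over the settings 3.4e-05 to 0.0527). The median log2 difference was 1.08 (camera adjusted p = 0.00699, adjusted p = 0.401 with an estimated correlation). After quantile normalization the list no longer passed (median 0.92, adjusted p = 0.067). With no filter that median lay at percentile 88.2 of random lists matched on knockout signal (95% of them 0.18 to 1.14), so the upward shift of the list is not told apart from chance there. Genes for cytosolic ribosomal proteins were lower, with 16 of 19 falling, 2 rising and 1 not passing over all genes, and 16 falling and 3 rising adjusted over the list alone. The log2 difference was -5.87 (SE 0.35) for Rpl37, -4.08 (SE 0.19) for Rps19, -2.66 (SE 0.20) for Rps20 and -2.59 (SE 0.20) for Rps24, and after quantile normalization it was -1.32 for Rps19, 0.48 for Rps20 and 0.01 for Rps24. That of Rpl37, with low knockout signals, ran from -6.84 to -4.86 over the settings. The list's median of -1.997 (camera adjusted p = 0.00117, adjusted p = 0.664 with an estimated correlation) turned to 0.49 after quantile normalization, which no longer passed (adjusted p = 0.448) and lay at percentile 13.8 of such random lists. On the wild-type arrays the brightest 1% of probe sets held 54.1% and 53.3% of all signal, against 15.9% to 20.3% on the knockout DMSO arrays.

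Heat shock genes moved both ways between genotypes, with 8 of 28 higher, 8 lower and 12 not passing, where 65.0% of all genes tested passed. Hspb1 and Hspa8, which encode a small heat shock protein and the constitutive HSC70 chaperone, fell, with log2 differences of -2.67 (SE 0.27) and -2.36 (SE 0.24). Serpinh1, which encodes a collagen chaperone, rose by 2.18 (SE 0.31) and Stip1, which encodes the HSP70 to HSP90 adaptor HOP, by 2.14 (SE 0.20). After quantile normalization the difference of Hspa8 was 0.61, and with probe sets open to cross-hybridisation avoided that of Serpinh1 was 3.19. The list did not pass camera (adjusted p = 0.85, 0.943 with an estimated correlation).

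With an offset of 32 the 8 largest rises belonged to Baz2a, C1s1, Cetn4, Cd28, Ttll1, Htra1, Kitl and Lgmn. Baz2a, which encodes a subunit of a chromatin remodelling complex, rose 48.9-fold (log2 difference 5.61, SE 0.15) and C1s1, which encodes a complement protease, 48.1-fold. The order and size of such rises depend on the offset, since wild-type signals were low. Cetn4, a centrin gene, had wild-type signals of 11.2 and 10.1, and its log2 difference of 5.50 ran from 1.56 to 7.35 over the settings. The lower end is the mean of its probe sets, whose differences were 5.50 and -2.38, and does not come from the offset. That of Lgmn, which encodes the protease legumain, was 5.07 and ran from 4.10 to 5.99. That of Kitl was 4.12 without wild-type replicate 1 and 6.10 without wild-type replicate 2. At the same offset the 8 largest falls belonged to Hoxd10, Rai2, Fign, D2hgdh, Ddn, Zfp711, S1pr3 and Pou3f3. Their sizes depend on the settings, and for Hoxd10, Fign, Zfp711, S1pr3 and Pou3f3 the knockout signals lay below the offset. Over the settings the log2 difference ran from -9.06 to -6.80 for Rai2, from -8.13 to -6.03 for Fign, which encodes a microtubule-severing ATPase, from -7.40 to -5.61 for S1pr3, a receptor for sphingosine 1-phosphate, from -7.79 to -5.64 for Zfp711 and from -8.93 to -5.53 for Pou3f3, a neural POU-domain transcription factor. Several of these calls rest on the probe set chosen. The probe sets of Baz2a, Cetn4, D2hgdh, Kif11, Men1, Rps20 and Rps24 disagreed in sign, 7 of the 23 named genes with 2 or more. With probe sets open to cross-hybridisation avoided, the difference of D2hgdh was 1.14 instead of -7.81 and Baz2a no longer passed (0.40, adjusted p = 0.307).

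In all, 8075 of 12427 genes passed at an adjusted p of 0.05 (limma with Benjamini-Hochberg adjustment), 4373 higher and 3702 lower in knockout cells. On simulated data with each group at its own spread, this fit called more unchanged than changed genes. The adjusted p-values between genotypes may therefore not hold their nominal error rate. The simulation does not settle this, since it took SDs observed on 2 wild-type arrays as true and shuffled them over genes. How many of the 8075 calls are false was not estimated, since far fewer genes were changed in the simulation. The arrays of the groups did not overlap for 9658 genes (77.7%), where chance gives 20%. The median difference over all genes was 0.22 on the log2 scale, and median centring changed the share of calls that were higher from 54.2% to 46.8%. Because both wild-type arrays stood apart technically, array quality and genotype fell together, and no count could be made without those arrays. Among bright genes, 94 with no human gene of the same symbol had a median log2 difference of 1.55 after quantile normalization, against 0.60 for the rest.

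The drug comparison asks which transcripts respond to HSP90 inhibition in cells that lack MLL1. The heat shock response, the set of chaperone genes driven by heat shock factors, shifted upwards on the AUY922 array. Of 28 measured heat shock genes 26 had positive differences and the median was 1.02 on the log2 scale, a 2.03-fold change. Adjusted over the list alone 20 rose and 0 fell, whereas over all genes tested none passed (limma, Benjamini-Hochberg). Fitted to the 4 knockout arrays alone, 11 rose over all genes and 21 adjusted over the list alone. Hspa4l, which encodes an HSP110-type chaperone, went from a mean signal of 360.1 ± 48.2 (SD, n = 3) to 2717 (n = 1), a 7.05-fold rise (log2 difference 2.82, SE 0.30, limma adjusted p = 0.388 over all 6 arrays and 0.015 in the knockout arrays alone). Hspb1 was 6.22-fold higher (2.64, SE 0.34), Hspa1b, which encodes the inducible chaperone HSP70, 6.09-fold (2.61, SE 0.35, and 3.33 after quantile normalization) and Dnaja4, an HSP40-type co-chaperone gene, 4.44-fold (2.15, SE 0.28), each with an adjusted p between 0.015 and 0.0339 in the knockout arrays alone.

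The list passed camera at an adjusted p of 1.6e-33 (adjusted p = 0.176 with an estimated correlation), and its median exceeded those of all 10000 random lists matched on signal. Each knockout DMSO array set in the same way against the other 2 gave list medians of 0.13, -0.11 and -0.06. Among further genes with large moderated t, Chordc1 and Ahsa1, which encode HSP90 co-chaperones, were 2.53-fold and 2.81-fold higher. Both are members of the heat shock list and are already counted in it. Outside that list Tmem33, which encodes a membrane protein of the endoplasmic reticulum, was 2.74-fold higher and Fermt3, which encodes the integrin activator kindlin-3, 3.97-fold higher. All 4 passed in the knockout arrays alone (adjusted p = 0.0272 to 0.0342) and not over all 6 arrays.

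**Figure D3:**
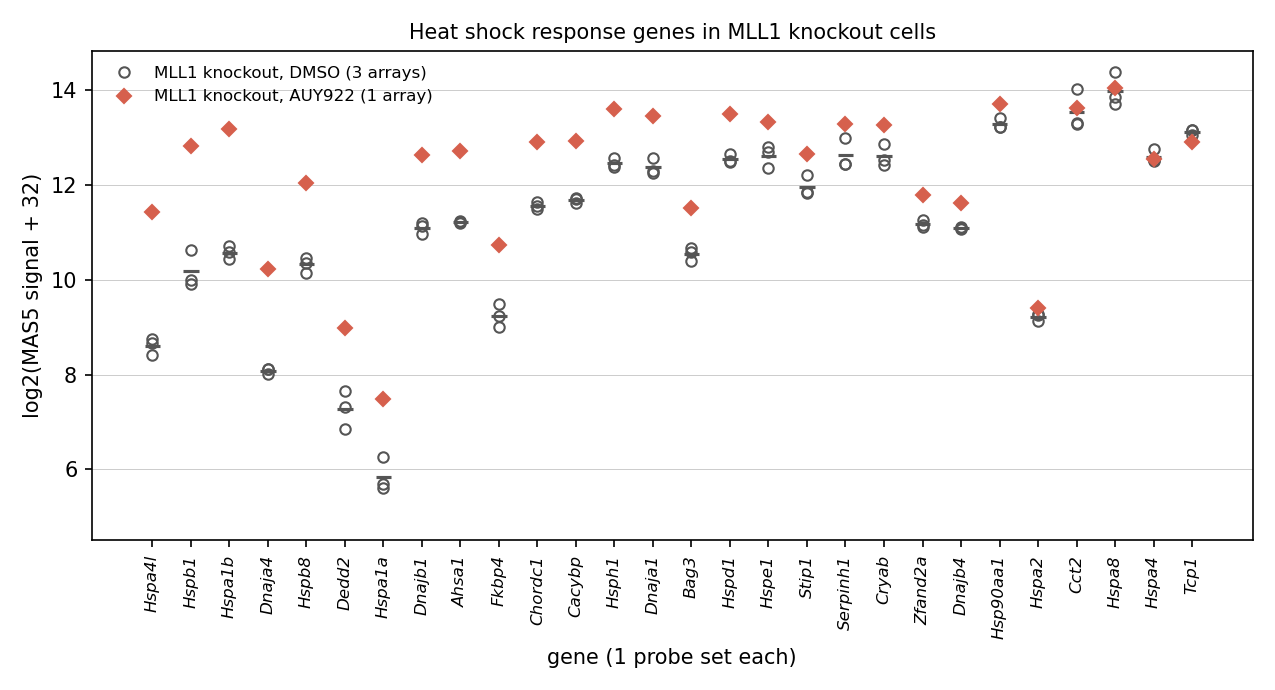
Signal, as log2(MAS5 signal + 32), of the 28 measured heat shock genes on the knockout arrays, with DMSO arrays as circles, their mean as a bar and the AUY922 array as a diamond. The diamond lies above the bar for 26 genes and furthest above it for Hspa4l, Hspb1 and Hspa1b.

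The 8 genes with the largest negative moderated t were Pmepa1, Id3, Egr2, Hdac5, Zc3h12a, Pld2, Id2 and Mta1. Id2 and Id3, which encode inhibitors of basic helix-loop-helix factors, were lower on the AUY922 array, Id2 with a mean signal of 1157 ± 207.4 (SD, n = 3) in DMSO and 262.2 in AUY922 and Id3 by 2.67-fold, and Pmepa1, a transforming growth factor beta target gene, was 3.23-fold lower. Egr2, an immediate-early zinc finger factor gene, was 4.38-fold lower and Zc3h12a, which encodes an RNase that degrades inflammatory mRNAs, 4.40-fold lower. Hdac5, a class II histone deacetylase gene, was 3.33-fold lower, Pld2, a phospholipase D gene, 2.66-fold and Mta1, a gene of the NuRD complex, 2.37-fold. With the mean of its probe sets Zc3h12a was at -1.22 on the log2 scale, and with probe sets open to cross-hybridisation avoided Pld2 was at -0.63 against -1.41. These 8 genes had adjusted p of 0.388 to 0.415 over all 6 arrays and of 0.0158 to 0.0388 in the knockout arrays alone (limma).

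Immediate-early genes, which respond to growth factor signalling within minutes, were lower as a group (median -0.53, camera adjusted p = 2.9e-05, adjusted p = 0.253 with an estimated correlation). Of 27 measured, 19 had negative differences. For this list and the others that follow, medians of lone knockout DMSO arrays were not computed. Chance spread of a single array is therefore not set aside for them. Adjusted over the list alone 5 fell, and over all genes none passed. In the knockout arrays alone 13 fell and 2 rose adjusted over the list alone, and 5 fell over all genes. The 5 were Egr2, Klf2 (4.15-fold lower), Ier3 (2.23-fold lower), Jund and Dusp6, the last pair named after their values were seen. Fos had a log2 difference of -1.52 and did not pass there (limma adjusted p = 0.0577, range over the settings 0.00232 to 1). Inflammatory targets of NF-kappaB were also lower (14 genes, median -0.51, camera adjusted p = 0.00941, 0.4 with an estimated correlation), with the chemokine gene Cxcl1 2.20-fold, the inhibitor gene Nfkbia 1.85-fold, the chemokine gene Ccl2 1.73-fold and Tnfaip3 1.70-fold lower. With the replicate number as a block the median of these targets was -0.061. Glycolysis and hypoxia genes had a median of -0.33 with 18 of 20 negative (camera adjusted p = 1.1e-04, 0.418 with an estimated correlation), and of -0.19 without knockout DMSO replicate 1. In that list Hk2, a hexokinase gene, was 1.74-fold, Pfkp 1.67-fold, and Egln3 and Pfkfb3 each 1.58-fold lower. None of the genes of these 2 lists passed in the fit of all 6 arrays, over all genes or adjusted over the list alone. In the knockout arrays alone 1, Cxcl1, passed over all genes (adjusted p = 0.0388, limma), and 2 NF-kappaB targets and 5 glycolysis and hypoxia genes fell adjusted over the list alone.

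Stress programmes other than the heat shock response had medians in both directions on the AUY922 array. Lone knockout DMSO arrays were not examined for these lists. For the BMP and TGF-beta target lists described last, such arrays gave medians as far out as 0.27 and -0.22. The integrated stress response, the programme downstream of ATF4, was higher (18 genes, median 0.38, camera adjusted p = 8.6e-05, 0.301 with an estimated correlation), with Slc7a11, Cebpb, Trib3 and Asns 1.69-fold to 1.91-fold higher. The NRF2 oxidative stress list was higher (16 genes, median 0.32, camera adjusted p = 4.7e-04, 0.301 with an estimated correlation), with the glutathione synthesis genes Gclm and Gclc 1.77-fold and 1.69-fold and Gsta4 1.42-fold higher. The unfolded protein response of the endoplasmic reticulum was lower (20 genes, median -0.21, camera adjusted p = 0.0186, 0.301 with an estimated correlation). Within it Xbp1, Dnajb9 and Sdf2l1 were 2.15-fold, 1.62-fold and 1.60-fold lower and Hyou1 1.53-fold higher. Over the settings their log2 differences ran from -1.29 to -0.81, -0.84 to -0.17, -0.75 to -0.37 and 0.23 to 0.71, in that order, and that of Gclm from 0.59 to 1.82. No single gene of these 3 lists passed over all 6 arrays, either over all genes or adjusted over the list alone. In the knockout arrays alone none passed over all genes, and adjusted over the list alone 1 rose in each of the first 2 lists and 5 fell and 2 rose in the third.

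Smooth muscle and myofibroblast markers were lower (9 genes, median -0.23, camera adjusted p = 0.034, 0.442 with an estimated correlation), with Smtn 2.03-fold, Des 1.44-fold and Lmod1 1.34-fold lower and Tpm2 at a log2 difference of -0.59. Oxidative phosphorylation genes were slightly lower (24 genes, median -0.13, camera adjusted p = 0.034, 0.513 with an estimated correlation), with Cyc1 1.36-fold, Atp5o and Uqcrc1 each 1.24-fold and Ndufb5 1.23-fold lower. The latter call was lost in the knockout arrays alone (adjusted p = 0.115), without either wild-type array and without knockout DMSO replicate 1. The smooth muscle call was lost without either wild-type array and without knockout DMSO replicate 2, and its median was -0.15 with an offset of 100. No gene of these 2 lists passed over all genes or adjusted over the list alone in the fit of all 6 arrays, and Smtn passed in the knockout arrays alone (adjusted p = 0.0449).

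Hox genes and the MLL complex genes did not pass as lists on the AUY922 array. The HoxA list had a median of -0.11 with camera's direction upwards (adjusted p = 0.763), the other Hox clusters one of -0.22 (0.232) and the MLL complex list one of -0.13 (0.441), with adjusted p of 0.807, 0.442 and 0.542 with an estimated correlation. Differences in them included -1.15 (SE 0.53) for Hoxc5, -0.87 (SE 0.64) for Hoxb3, -0.79 (SE 0.44) for Hoxa9, -0.73 (SE 0.47) for Hoxa3, 0.76 (SE 0.26) for Rbbp5 and -0.69 (SE 0.41) for Men1. Over the settings that of Hoxb3 ran from -1.17 to -0.13. Kmt2a differed by -0.17 (SE 0.53). The probe sets of Hoxa3, Hoxa5, Hyou1, Kdm6a, Kmt2a and Ndufb5 disagreed in sign, 6 of the 36 named genes with 2 or more.

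Over all 6 arrays 0 of 12427 genes passed (limma with Benjamini-Hochberg adjustment, smallest adjusted p = 0.388), with 532 at an unadjusted p under 0.05, 225 of them higher and 307 lower. In the knockout arrays alone 115 passed, 51 higher and 64 lower. There the spread comes from the knockout DMSO arrays, which varied less than the wild-type arrays (median SD 0.15 against 0.33 on the log2 scale). The same holds when either wild-type array is left out, so those fits are no separate check. Over all 6 arrays the count was 1373 with array weights and 2 after quantile normalization. The arrays of the groups did not overlap for 7774 genes (62.6%), where chance gives 50%. By size alone, 230 genes differed by 1 or more on the log2 scale, 89 higher and 141 lower. The knockout DMSO arrays, each against the other 2, gave 75, 3 and 5 such genes. With an offset of 1 these counts were 323, 107 and 108 against 423 on the AUY922 array. Among 3684 probe sets without a gene name the AUY922 array gave 53 and the knockout DMSO arrays 67, 12 and 9. The AUY922 group is a single array with no replicate check, assumed to vary like the other groups.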

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

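The tests of 3' bias, of a compression of signal and of the AUY922 array's quality were chosen only after the results they bear on were seen. Control signals outside the comparisons set the wild-type arrays apart from the knockout DMSO arrays. The scaled signal of the hybridisation controls was 16.2-fold higher on them, the Gapdh 3'/5' ratio was 9.06-fold higher and the Actb 3'/5' ratio 6.80-fold higher.

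The 8075 genes called between genotypes were weighed first. A compression of signal common to all probe sets was argued against as the whole cause, since 7457 of 12469 genes were called after quantile normalization. That step removes any such trend. Of the 8075 calls 76.3% (6158) were among them, counted without regard to direction, and Hspa8 and Rps20 passed in both with opposite signs. With so many genes called after it, a large overlap was likely in any case, so nothing is concluded from the overlap itself. Distortion of single probe sets on the wild-type arrays stays open, because the intraclass correlation of the genotype difference over probe sets of the same gene was 0.197 (95% bootstrap interval 0.174 to 0.217, 5876 genes), against 0.475 for the drug difference. So does 3' bias of the labelled RNA, as the lowest wild-type 3'/5' ratio was 5.05 times the highest knockout ratio for Actb, the smaller of both controls. RNA of another species on the wild-type arrays may also contribute, because the 94 bright genes with no human gene of the same symbol had a median at percentile 100 of random lists (1.55, random lists 0.29 to 0.96), although these genes could also differ between mouse lines and no sequence was compared, and an effect of the genotype stays open as well.

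The fall of the Hox genes in knockout cells was weighed next. Raised signal of dim probe sets on the wild-type arrays was argued against, since the median of 33 Hox genes (-2.81) lay at percentile 0 of random lists matched on knockout signal (-1.04 to 0.12). A few distorted probe sets were argued against as well, since 62.5% of the Hox probe sets (30 of 48) had both wild-type arrays above all knockout DMSO arrays, against a mean of 33.4% in random sets. RNA of another species and 3' bias were not tested on the Hox probe sets and stay open. A loss of expression with MLL1 may account for the fall and stays a hypothesis.

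The heat shock genes higher on the AUY922 array were weighed last. Chance spread of a single array was argued against, since the largest list median of a lone knockout DMSO array was 0.132 of the smallest AUY922 median. So were array brightness and RNA quality, since the AUY922 array lay within the range of the knockout DMSO arrays (factor 1) in hybridisation controls and Gapdh 3'/5' ratio. Cross-hybridising probe sets were argued against too, since the 51 heat shock probe sets without suffixes for shared sequences had a median of 1.18 (random sets -0.13 to 0.06). A response of the cells to AUY922 is a hypothesis that could account for the rise, found and tested on 1 treated array.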

How the results depend on the processing

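The knockout arrays alone for the gene lists, the knockout arrays alone with quantile normalization and a filter of their own, and quantile normalization with no filter were chosen after seeing the data. Of 753 values of named genes in the genotype comparison 742 kept their direction and side of the threshold, 3 no longer passed and 8 reversed. Of 1174 in the drug comparison 1043 kept both, 126 came to pass and 5 reversed. For gene lists these were 243 of 285 and 274 of 311. The Kmt2a genotype difference ranged from -2.71 to -1.56, both ends from leaving out a wild-type array. Leaving out 1 knockout DMSO array gave 6547 to 7034 genes called between genotypes. Without a wild-type array that group has 1 array left, and the spread comes from the knockout arrays, the less variable group. Counts from such fits are not set beside the others. Where a value changed, the cause was not tested unless given.

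The genotype count was 12622 with no filter on dim probe sets (35.0% higher) and 16650 with every probe set on its own, where more features were tested. The share higher was 68.0% with the upper 40% of probe sets. The median difference over all genes was 0.33 after quantile normalization, -0.62 with no filter and 0.52 with the upper 40%. The lists past the threshold numbered 0 with an estimated correlation and 20 with fry for genotype, and 0 and 1 for the drug. The drug count was 2 after quantile normalization, 1373 with array weights, 115 in the knockout arrays alone and 126 in these with quantile normalization and their own filter, and 0 to 114 without 1 array. Genes differing by 1 or more on the AUY922 array numbered 423 with an offset of 1 and 134 with an offset of 100, and the lone knockout DMSO arrays gave 323, 107 and 108 with the former and 33, 2 and 3 with the latter.

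Reversed results are given as log2 differences, for lists as medians, where camera's or fry's direction turned and the median can keep its sign. With fry these were immediate-early genes (0.66) and other MLL1-associated targets (0.62) for genotype. With an offset of 1 they were the MLL complex list for genotype (-0.26) and HoxA for the drug (-0.26). After quantile normalization they were, for genotype, Rps20 (0.48), Rps24 (0.011) and Hspa8 (0.61), alike with no filter, and the lists of heat shock (-0.10), immediate-early genes (0.35), other MLL1-associated targets (0.68), MLL complexes (-0.17), fibroblast matrix (0.41) and cytosolic ribosome (0.49), and for the drug skeletal muscle (0.11) and cytosolic ribosome (0.073). With the mean of probe sets the drug difference of Kmt2a was 0.23. With probe sets open to cross-hybridisation avoided, D2hgdh (1.14) and Rps24 (2.30) reversed for genotype and Hoxa5 (-0.054) for the drug. In the knockout arrays alone with quantile normalization Hoxa3 was 0.34 for the drug.

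Leaving out 1 array gave ranges of -0.26 to 0.24 for MLL complexes, -0.44 to 0.075 for heat shock factors and co-chaperones and 0.055 to 0.32 for smooth muscle markers between genotypes, each reversed without wild-type replicate 1. For the drug the ranges were -0.046 to 0.21 for macrophage markers and -0.19 to 0.027 for cytosolic ribosome, each reversed without knockout DMSO replicate 1, and -0.33 to 0.057 for Kmt2a, reversed without replicate 2. The call of Ccne2 ended without knockout DMSO replicate 1 (adjusted p = 0.0527, range over the settings 3.4e-05 to 0.0527).

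With the replicate number as a block, a pairing the labels do not state, 6574 and 0 genes and 6 and 8 lists passed for genotype and drug. Reversed then were the integrated stress response for genotype (-0.052) and, for the drug, Hoxb4 (0.024), proteasome (-0.092), heat shock factors and co-chaperones (-0.19) and skeletal muscle (0.33). NF-kappaB targets had a drug median of -0.061, against -0.56 to -0.43 over the other settings. Zfp711, S1pr3 and Hoxa11 (offset 1 and upper 40% filter), Hoxc9, Slc7a11, Lmod1 and Hoxb2 (upper 40% filter) and Hoxc5 (offset 100, quantile normalization and upper 40% filter) fell below the filter and gave no value there.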

Other observations

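The BMP and TGF-beta gene lists were chosen after Id1 to Id4 and Pmepa1 had been seen. Among lists not yet described, none passed camera between genotypes. Single members that passed are counted below (limma, adjusted over all genes), to be set beside the 65.0% of all genes tested that passed. Glycolysis and hypoxia genes had 10 of 20 higher and 2 lower (median 0.84, adjusted p = 0.0577), with Egln3 at 3.16 and Pdk1 at 2.89. After quantile normalization that list passed camera's preset correlation (median 1.67, adjusted p = 0.00829). Before it, the list had an adjusted p = 0.664 with an estimated correlation, which was not computed after it. NF-kappaB targets had 8 of 14 higher and 1 lower (1.16, 0.222), led by Cxcl5 at 3.97, and p53 targets 12 of 19 higher and 4 lower (1.11, 0.138), among them Mdm2 at 2.17. NRF2 targets had 7 of 16 higher and 0 lower (0.38, 0.222). Proteasome genes had 4 of 31 higher and 12 lower (-0.29, 0.0647) and cholesterol synthesis genes 2 of 16 higher and 6 lower (-0.48, 0.264). The unfolded protein response had 7 of 20 higher and 5 lower (0.33, 0.675), the integrated stress response 5 and 5 of 18 (-0.05, 0.85), immediate-early genes 12 and 8 of 27 (0.66, 0.85), interferon genes 7 and 4 of 23 (0.63, 0.759) and oxidative phosphorylation 3 and 5 of 24 (-0.09, 0.74). Heat shock factors and HSP90 co-chaperones had 4 and 3 of 15 (-0.01, 0.85) and other MLL1-associated targets 5 and 3 of 11 (0.62, 0.85), where Meis2 fell by 5.62 and Eya4 rose by 2.20. Adjusted over the list alone the counts were the same, except 6 and 3 for other MLL1-associated targets. Mean and median differed in sign for the integrated stress response, other MLL1-associated targets and fibroblast matrix.

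Cell type markers moved both ways between genotypes. Fibroblast matrix genes had 7 of 24 higher and 7 lower (0.08, 0.85), with Lox at 2.26 and Vim at -3.70. Smooth muscle markers had 4 and 2 of 9 (0.19, 0.85), or 4 and 3 adjusted over the list alone. Skeletal muscle had 1 and 4 of 5 (-2.83, 0.185), neural markers 3 and 4 of 7 (-2.48, 0.675), macrophage markers 3 and 4 of 7 (-1.78, 0.735), epithelial markers 1 and 4 of 8 (-1.63, 0.22) and cartilage and bone markers 1 and 3 of 5 (-1.54, 0.23). Too few for the test were endothelial (1 and 2 of 4), adipocyte (1 and 0 of 4) and prostate markers (1 and 2 of 4). The wild-type arrays of all these counts are those with the raised 3'/5' ratios.

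On the AUY922 array none of the lists below passed camera in the main setting and no member passed over all genes in the fit of all 6 arrays. Cytosolic ribosome, proteasome and other MLL1-associated targets each passed camera in an alternative setting, 3 of the 311 list values of the drug comparison. The medians and adjusted p were 0.06 (0.333) for proteasome, 0.12 (0.441) for p53 targets, -0.02 (0.376) for the cell cycle, 0.07 (0.232) for interferon genes, 0.03 (0.399) for cholesterol synthesis, -0.14 (0.0787) for other MLL1-associated targets, 0.00 (0.528) for heat shock factors and co-chaperones and -0.09 (0.613) for cytosolic ribosome. Among cell type markers they were -0.08 (0.416) for fibroblast matrix, 0.33 (0.757) for skeletal muscle, -0.06 (0.232) for neural, 0.09 (0.724) for macrophage, -0.07 (0.416) for epithelial and 0.22 (0.613) for cartilage and bone. Endothelial, adipocyte and prostate markers had medians of -0.02, -0.43 and -0.24. Adjusted over the list alone 2 neural markers fell and 1 co-chaperone gene, Ahsa2, rose by 1.77. In the knockout arrays alone Ifit1 passed (1.70, adjusted p = 0.0415), as did Tubb3 (-1.33, 0.0388) and Ahsa2 (0.0388).

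Id1 and Id4 were lower with Id2 and Id3 on the AUY922 array (-1.29 and -1.50, adjusted p = 0.0388 and 0.0446 in the knockout arrays alone, limma). A lower expression of BMP target genes as a group may account for this, since 7 other BMP targets measured had a median of -0.50 at percentile 0.08 of random lists, with Smad7 at -2.86 and Smad6 at -1.07. For Pmepa1, lower expression of TGF-beta target genes as a group is likewise a candidate explanation, since 9 other targets had a median of -0.44 at percentile 0.08, with Ldlrad4 at -1.10 and Skil at -1.03. In each list 6 genes were negative, and none passed on its own in the knockout arrays alone. Lone knockout DMSO arrays gave medians of 0.11, -0.03 and 0.27 for BMP targets and of -0.22, 0.08 and 0.11 for TGF-beta targets. Chance spread of a single array is thus not set aside for either list, and both hypotheses rest on 1 treated array.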
